A study of Mus musculus with 8 samples.

How the data were processed

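RNA of the outer renal cortex of wild-type C57Bl6/J mice was sequenced after 9 weeks on a high fat diet or a control diet, with 4 libraries per diet. Per the labels, the diets began at 6 weeks of age, so the mice were 15 weeks old, and libraries were made with a TruSeq kit that removes ribosomal RNA (Ribo-Zero Gold) from 1 ug of total RNA. Libraries are named here by diet and by the letter in their label, which differs between the diets, so no pairing of libraries was used. Each library title holds an M between the diet and the letter, which may stand for male but is not explained. The labels otherwise state neither the sex of the mice nor that each library came from a separate mouse. The p-values measure only the spread between these libraries.

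Per the submitters' processing notes, CASAVA 1.8.2 and RSEM 1.2.9 were used with the mm10 build. The authors deposited RSEM expected counts per gene symbol, which are estimated and need not be whole numbers; RSEM shares reads between similar genes by likelihood. The authors also deposited FPKM values for the same gene symbols, in a table named for isoforms that holds 1 line per gene, so isoforms were not compared. A pair of further deposited tables, named by the authors as comparisons, give a fold (ratio of high fat over control) and a posterior probability of equal expression as a score for each listed gene, and one of them adds FPKM values by Ensembl gene. The tool behind these tables is not given in the sources used here. The coordinates in the Ensembl table overlapped those of the same gene in GENCODE M21 (GRCm38, the assembly of mm10) for 152 of 1145 genes, although all 1145 were on the same chromosome, so those coordinates were not used. Positions given here are gene bounds in GENCODE M21 on GRCm38.

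Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM factors, genes kept by filterByExpr, diet as the only term). Of 23504 gene symbols, 14710 were tested, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the size of the log2 fold change divided by the square root of F. Levels are TMM-normalized counts scaled to 1e6 per library (CPM), as mean ± SD of 4 libraries. Total expected counts per library ran from 23503593 to 30781585, so a gene at 1 CPM rests on few counts. On simulated counts with the means, spreads and depths of this comparison, run on 14604 genes, the test recovered 28% of genes changed by 1.3-fold, 78% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, and 10.1% of its calls were unchanged genes, above the 5% aimed at. This was 1 draw in which genes varied independently and 200 were set to these folds, fewer than the 1468 called in the data. Recovery and the share of false calls may therefore differ in the real comparison.

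Before the data were examined, 44 gene lists were fixed (kidney cell types, tissues that could be carried in with the cortex, and pathways of lipid, glucose, stress and transport). The 42 lists with at least 4 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry. Symbols of list genes were matched through RefSeq synonyms; 14 list genes found no match and were not analysed here, among them Igkc and the olfactory receptors Olfr78 and Olfr1393. Fat, muscle and red cell RNA was compared as the log2 sum of CPM over each list, with an exact two-sided permutation test over 70 splits, which cannot give a p under 0.0286; brown fat, adrenal and liver sums were added after the data were seen.

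Genes are named by a rule fixed beforehand: the 15 largest rises and 15 largest falls among called genes with a mean of at least 1 CPM in the higher group and no overlap between the diets (86 predicted genes, pseudogenes and small RNAs were left out of this part); up to the 4 called genes with the smallest p in each list; and 27 genes fixed in advance whatever their result. Other genes are named only as members of a list whose count they belong to, or are said to have been chosen after their values were seen. Alternatives fixed beforehand were DESeq2 size factors, DESeq2 1.42.0 (Wald test), limma-voom, limma on log2(FPKM + 0.1) for genes with a mean of at least 0.5, no filter on low counts, a mean of at least 5 CPM, other thresholds, and leaving out each library. Added after the data were seen were a robust quasi-likelihood fit, leaving out ribosomal and structural RNA, removing the trend of counts with transcript length in each library, rescaled FPKM, log2 FPKM with pseudocounts of 1 and 0.01, leaving out control J with high fat G, and a red cell sum over fewer genes. Results for some genes that the rule names are not reported here.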

Results

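The renal cortex of mice fed a high fat diet or a control diet for 9 weeks was compared by RNA sequencing, with 4 libraries per diet. The stated purpose was to find genes whose expression differed between the diets at 15 weeks of age. Total expected counts were 25287100 ± 1298610 (SD, n = 4) on the high fat diet and 28419362 ± 1744100 (SD, n = 4) on the control diet, a difference in depth with an exact two-sided permutation p = 0.0286, the smallest that 70 splits can give. In the control library J, 50.3% of counts came from Rn45s, the precursor of ribosomal RNA, against 1.23% to 13.3% in the other 7 libraries, which left fewer counts for other genes. The first principal component, with 38.4% of the variance of log2 CPM, placed all 4 control libraries below 0 and all 4 high fat libraries above 0.

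**Figure D1:**
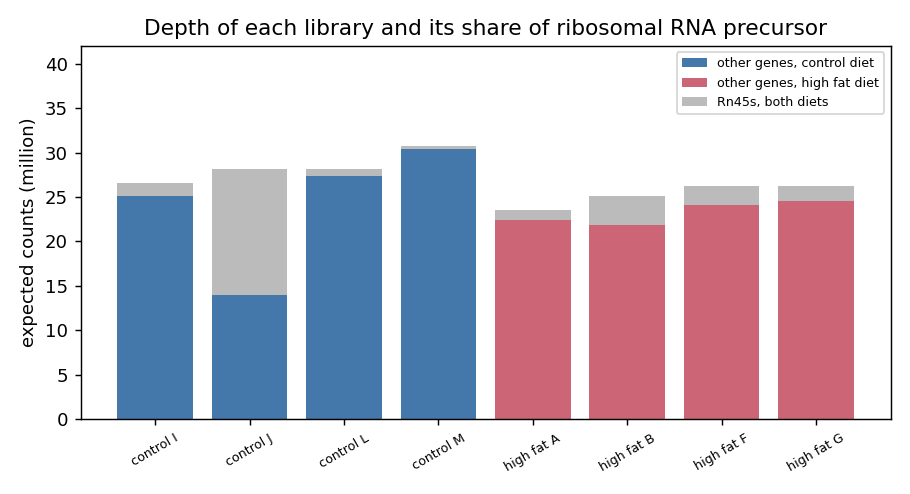
Expected counts, in units of 1e6 (vertical axis), for each of the 8 libraries (horizontal axis). The coloured part of a bar is all genes but Rn45s and the grey part is Rn45s, which took 50.3% of control J.

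Of 14710 genes tested, 1468 passed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 715 rose and 753 fell on the high fat diet. Most changes were small: the median fold of called genes was 1.31, and 257 genes rose and 148 fell by at least 1.5-fold. In 1361 of the called genes the 4 values of one diet lay entirely outside those of the other, a separation that 17.5% of tested genes showed and that chance gives to 2.86%. All 1468 genes kept their direction when any single library was left out, which for the separated genes follows largely from the separation. The number called then ran from 737 (without high fat F) to 1501 (without control M). It was 774 without control I, 806 without control J, 880 without high fat G, 943 without high fat A and 957 without control L.

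Among the genes with the largest rises were several that were nearly silent on the control diet. Synpr, which encodes the synaptic vesicle protein synaptoporin (chromosome 14, 13284780 to 13616340), rose from 0.425 ± 0.422 to 18.7 ± 17.6 CPM (SD, n = 4), a log2 fold change of 5.23 ± 0.76 (SE) with adjusted p = 0.0036 in edgeR. High fat F, at 44.9 CPM, stood apart from the other 3 libraries of its diet. Ctxn3, encoding cortexin 3 (chromosome 18, 57468516 to 57478133), rose from 1.76 ± 1.38 to 20.5 ± 5.40 CPM (SD, n = 4), a log2 fold change of 3.40 that was 4.13 without control M. The chemokine gene Ccl28 (chromosome 13, 119623819 to 119654359) rose from 8.03 ± 6.09 to 45.5 ± 18.9 CPM (SD, n = 4), by 2.42 on the log2 scale and by 3.09 without control M. The log2 fold change of Synpr was 5.91 without control M and 4.34 without high fat F. Popdc3, Atp12a (the non-gastric proton and potassium pump), Smoc1, Sorcs1, Ntng1 and Iqgap3 rose as well, each to a mean under 3 CPM. The log2 fold change of Atp12a went from 4.42 to 6.14 without control I and that of Sorcs1 from 2.40 to 3.03 without control M. Inhbb, the activin beta B subunit, reached 4.33 ± 1.41 CPM (SD, n = 4) from 1.06 ± 0.249. The deepest fall was that of Slc7a12, an amino acid transporter gene (chromosome 3, 14480697 to 14505830), from 7.05 ± 4.36 to 0.552 ± 0.215 CPM (SD, n = 4). Serpina1a fell from 10.97 ± 1.90 to 2.40 ± 1.08 CPM, the carboxylesterase gene Ces1g from 15.2 ± 5.67 to 3.24 ± 0.835, the betaine-homocysteine methyltransferase gene Bhmt from 6.88 ± 1.43 to 1.66 ± 0.401, and the water channel gene Aqp4 from 14.7 ± 3.21 to 3.94 ± 1.70 (SD, n = 4 for each). Lipg, Slc22a29, Kynu and BC089597 also fell. Of these genes, only Kynu lost its call in any fit without 1 library, with an adjusted p in edgeR of up to 0.0761, without control L; it was also lost without control J and without high fat A, F or G. Genes such as Serpina1a and Ces1g belong to families of close copies between which reads may be shared.

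**Figure D2:**
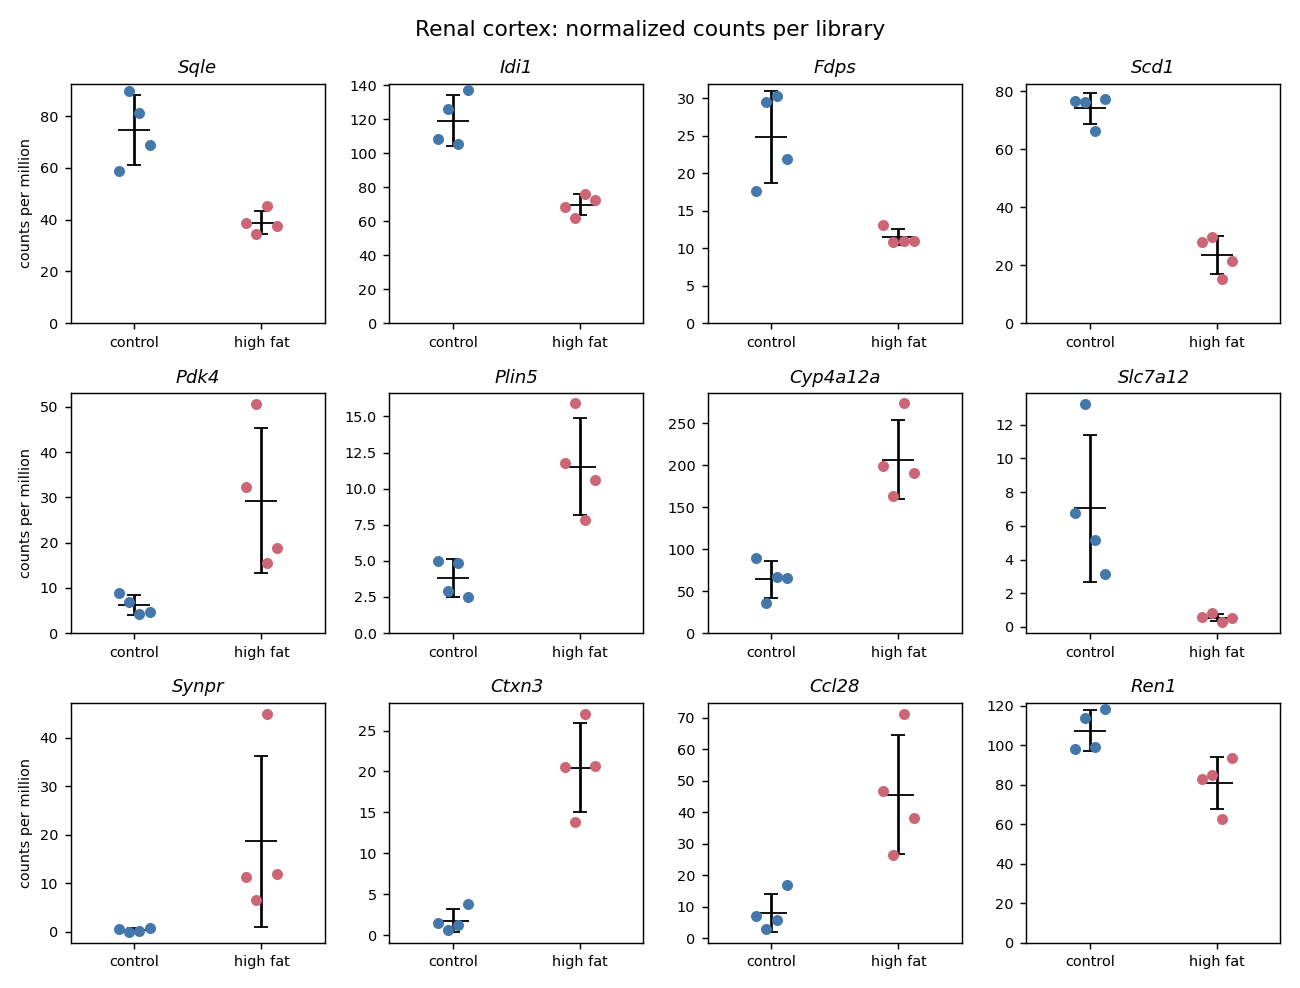
TMM-normalized counts per 1e6 counts (CPM; vertical axes, each with its own scale) of 12 genes in the control and high fat libraries. Points are libraries and black bars are the mean and SD of 4. Sqle lay at 74.7 CPM on the control diet and 38.9 CPM on the high fat diet.

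Of the 25 tested members of the list of cholesterol synthesis and uptake, 13 fell, none rose and 12 did not pass in edgeR. In all, 17 members had an unadjusted p under 0.05, all of them lower on the high fat diet. Sqle, squalene epoxidase (chromosome 15, 59315077 to 59331192), fell from 74.7 ± 13.7 to 38.9 ± 4.51 CPM (SD, n = 4), a log2 fold change of -0.94 ± 0.13 (SE) with adjusted p = 0.0024 in edgeR. Idi1, Fdps and Sc4mol (now Msmo1), all enzymes of the pathway, fell by 0.77, 1.11 and 1.54 on the log2 scale. In the related list of fatty acid and triglyceride synthesis 6 of 22 members fell and 3 rose, against 5 and 2 without control J and 3 and 1 without control J and high fat G. The desaturase genes Scd1 and Scd2 fell by 1.65 and 0.87 and Fads1 by 0.57, and Srebf1, a regulator of lipid synthesis genes, fell by 0.85, while Gpam, the first enzyme of glycerolipid synthesis, rose by 0.49. Srebf1 lost its call without control J (adjusted p = 0.0648 in edgeR) and without control L, high fat A or high fat B. With control J left out, 10 members of the cholesterol list fell, and 9 with high fat G left out as well, a setting added after the data were seen. The list tests gave an adjusted p = 8.09e-16 for cholesterol and 0.0172 for fatty acid synthesis (camera, preset correlation), against adjusted p = 0.217 and adjusted p = 0.245 with an estimated correlation. No list passed with an estimated correlation (8 at an unadjusted p under 0.05, and 13 passed with fry). At the preset correlation 15 lists were called between the diets. Of the 35 splits of the libraries into 4 and 4, 9, the diets included, called at least as many. Each comparison is therefore given as counts of called members, to be read beside the 9.98% called over all tested genes. Members that vary together can raise such counts as well.

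In the list of fatty acid oxidation genes and targets of the receptor PPARalpha, 10 of 36 tested members rose, none fell and 26 did not pass in edgeR, and 16 rose when p was adjusted over the list alone. In all, 18 members, all higher, had an unadjusted p under 0.05, and without control J 7 rose, or 5 without control J and high fat G. High fat F did not share the rise. Its median over the list, as log2 CPM relative to each gene's mean, was -0.12. That lay below control I (0.015) and L (-0.043) and above control J (-0.15) and M (-0.24). Between the diets these medians had an exact two-sided permutation p = 0.0857. Pdk4, whose product restrains glucose oxidation (chromosome 6, 5483351 to 5496309), rose from 6.14 ± 2.20 to 29.3 ± 15.96 CPM (SD, n = 4), a log2 fold change of 2.27 ± 0.37 (SE) with adjusted p = 0.0060 in edgeR. Ppara itself rose by 0.48, the carnitine palmitoyltransferase gene Cpt1a by 0.44, Acads by 0.36, the lipid droplet gene Plin2 by 0.41 and Angptl4 by 1.37 on the log2 scale. Plin2 lost its call without control J (adjusted p = 0.0513 in edgeR), and Angptl4 without control J, L or M and without high fat A or B (adjusted p up to 0.0786 in edgeR, without control L). Plin5, a lipid droplet gene (chromosome 17, 56111601 to 56117596), rose from 3.82 ± 1.29 to 11.5 ± 3.37 CPM (SD, n = 4). Cyp4a14 did not pass, at 55.5 ± 45.1 against 18.8 ± 11.9 CPM (SD, n = 4; adjusted p = 0.17 in edgeR), and its log2 fold change of 1.60 was 0.98 without high fat G. The list had an adjusted p = 1.61e-08 (camera, preset correlation), adjusted p = 0.0747 with fry and adjusted p = 0.403 with an estimated correlation. In the list of glucose production and transport 6 of 21 members rose and 1 fell. Pck1, the key enzyme of gluconeogenesis, rose from 2297 to 3758 CPM, by 0.71 on the log2 scale, Pcx by 0.47 and the sugar transporter gene Slc5a10 by 0.57, while Slc2a1 fell by 0.44. Without control J, 4 members rose and 1 fell, and without control J and high fat G 3 rose and 1 fell. That list had an adjusted p = 0.00282 (camera, preset correlation) and adjusted p = 0.184 with an estimated correlation.

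Among genes known to be higher in male than in female mouse kidney, 8 of 12 tested members rose, none fell and 4 did not pass in edgeR. Adjusted over the list alone, 10 rose and 1, Cyp7b1, fell by 0.93 on the log2 scale. Without control J, 7 rose, and without control J and high fat G, 4. Cyp4a12a, an arachidonate hydroxylase (chromosome 4, 115299046 to 115332815), rose from 64.2 ± 22.2 to 207 ± 47.1 CPM (SD, n = 4), a log2 fold change of 1.68 ± 0.23 (SE) with adjusted p = 0.0030 in edgeR. It may share reads with its near copy Cyp4a12b, so their split is uncertain. Gusb rose by 1.38, Acsm3 by 1.13 and the organic anion transporter gene Slco1a1 by 1.04 on the log2 scale. Kap, the abundant androgen-regulated kidney gene, did not pass, at 20853 ± 2131 against 17483 ± 2284 CPM (SD, n = 4; adjusted p = 0.22 in edgeR). The labels do not state the sex of the mice, apart from the unexplained M in every title. The summed CPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, chosen after the data were seen, ran from 175 to 186 over the 8 libraries, and Xist was at most 1.003 CPM. Of 8 female-biased members, Slc7a12 and Cyp2a4 fell and 6 did not pass. The male-biased list had an adjusted p = 8.71e-10 (camera, preset correlation) and adjusted p = 0.184 with an estimated correlation; the female-biased list had an adjusted p = 0.0636 and adjusted p = 0.433. Among cytochrome P450 and other xenobiotic enzymes, 7 of 32 members rose and 6 fell, with no common direction (adjusted p = 0.962, camera; adjusted p = 0.983 with an estimated correlation). Cyp2b10 rose by 2.79 (3.73 without control M), and Cyp2a5 and Cyp2c44 fell by 1.87 and 1.25. Reads may be shared between Cyp2a5 and Cyp2a4, both on chromosome 7. The fall of Cyp2a4 among the female-biased genes is therefore not certain to be separate from that of Cyp2a5.

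In the list of NRF2 targets and glutathione enzymes 9 of 24 members fell, 1 rose and 14 did not pass. Nqo1, a quinone reductase, fell from 78.3 ± 12.1 to 33.5 ± 3.37 CPM (SD, n = 4), and the glutathione transferase genes Gsta2, Gsta4 and Gstp1 fell by 1.69, 1.06 and 0.63 on the log2 scale. These transferases have close copies. Of 14 heat shock genes, 7 fell, none rose and 7 did not pass. The chaperone genes Hspa1a and Hspa1b, between which reads may be shared, fell by 1.38 and 1.51, and the cochaperone genes Dnaja1 and Stip1 by 0.57 and 0.45. Of 21 genes of endoplasmic reticulum stress, 7 fell, 1 rose and 13 did not pass, with Hspa5 falling by 0.62, Manf by 0.80, Sdf2l1 by 0.77 and Atf4 by 0.35. Without control J, 8, 6 and 4 members of these lists fell, and without control J and high fat G, 7, 3 and 1. The lists had adjusted p = 9.81e-08, 3.60e-09 and 0.00282 (camera, preset correlation), and adjusted p = 0.184, adjusted p = 0.245 and adjusted p = 0.245 with an estimated correlation. Of 19 immediate early genes Dusp1 and Zfp36 rose, Ier3 and Cyr61 fell and 15 did not pass (list adjusted p = 0.618, camera, and adjusted p = 0.834 with an estimated correlation). Zfp36 lost its call without control L or high fat A, and Cyr61 kept it in only 2 of 8 fits without a library, with an adjusted p up to 0.0886 without control I. The 28 ribosomal protein genes had a median log2 change of -0.20, with 5 called, all falls, and 23 not passing. Without control J 1 was called, and without control J and high fat G 0. The list's library medians overlapped between the diets, at -0.011 in control M and -0.0026 in high fat B (exact two-sided permutation p = 0.0571). Over all tested genes, log2 change rose with transcript length (Spearman rho 0.16 across genes, which are not independent replicates), from a median of -0.06 in the 1471 shortest genes to 0.06 in the 1471 longest. The ribosomal list had an adjusted p = 1.10e-07 (camera, preset correlation) and adjusted p = 0.433 with an estimated correlation.

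In the thick ascending limb list 6 of 12 members fell and 6 did not pass, led by Slc12a1, the sodium, potassium and chloride cotransporter, from 659 ± 53.8 to 457 ± 69.7 CPM (SD, n = 4); Cldn19, Ppp1r1a and Kcnj1 fell by 0.39, 0.39 and 0.30 on the log2 scale. Of 12 principal cell markers 3 fell, Aqp4, Scnn1g and Avpr2, and 9 did not pass, and of 13 intercalated cell markers Rhbg and Rhcg fell and 11 did not pass. Without control J and high fat G 1, 2 and 0 members of these 3 lists fell. Of 6 tested members of the medulla list, Cryab, Slc5a3 and Aqp1 fell, with 1 of them called without control J. The libraries are of outer cortex, where Aqp1 lay at 632 ± 32.8 CPM on the control diet (SD, n = 4). Its fall need not concern medulla. Slc5a3 overlaps Mrps6, which fell by 0.47 on the log2 scale, so these 2 falls may not be separate. Of 12 mesangial, smooth muscle and pericyte markers 3 fell, and 0 were called without control J (list adjusted p = 0.0318, camera, and adjusted p = 0.462 with an estimated correlation). Of 12 distal convoluted tubule markers Abca13 and Emx1 fell, and of 12 markers of the first proximal tubule segments 3 rose, Slc6a19, Slc4a4 and Cyp2e1. Of 12 markers of the last proximal segment, S3, Slc5a10, Slco1a1 and Acy3 rose and Slc7a12, Slc22a13 and Slc7a13 fell (list adjusted p = 0.756, camera, and adjusted p = 0.943 with an estimated correlation). Acy3 kept its call in 2 of 8 fits without a library and Slc7a13 in 4. Fits without a single library ended the calls of Kcnj1 (without control I or L and high fat F or G), Rhcg (without control I or J or high fat F), Emx1 and Slc5a3 (without 6 of 8 libraries each) and Aqp1 (without any), with adjusted p in edgeR up to 0.132. The thick ascending limb, principal cell and intercalated lists had adjusted p = 5.86e-07, 0.00282 and 0.0155 (camera, preset correlation), and adjusted p = 0.184, adjusted p = 0.184 and adjusted p = 0.403 with an estimated correlation (adjusted p = 0.0502 with fry for the intercalated list); the medulla, distal convoluted and first proximal lists had adjusted p = 0.0883, 0.654 and 0.0636, and adjusted p = 0.258, adjusted p = 0.931 and adjusted p = 0.245. In the renin-angiotensin list 3 of 11 members rose and 3 fell, against 1 and 2 without control J and 1 and 1 without control J and high fat G. The converting enzyme gene Ace rose from 142 ± 28.6 to 257 ± 44.7 CPM (SD, n = 4), while the peptidase genes Mme and Enpep fell by 0.52 and 0.34 on the log2 scale and Anpep rose by 0.55. Ren1, encoding renin (chromosome 1, 133350510 to 133360325), fell from 107 ± 10.3 to 81.0 ± 13.1 CPM (SD, n = 4; adjusted p = 0.043 in edgeR), a call kept in only 1 of 8 fits without a library, that without high fat G, with an adjusted p up to 0.101 without control J. Anpep lost its call without control I or J or high fat F or G, and Enpep without control I (adjusted p = 0.0513 in edgeR). Agt, Slc5a2 and the receptor gene Ffar3 did not pass, at adjusted p = 0.95, 0.43 and 0.32 in edgeR.

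**Figure D3:**
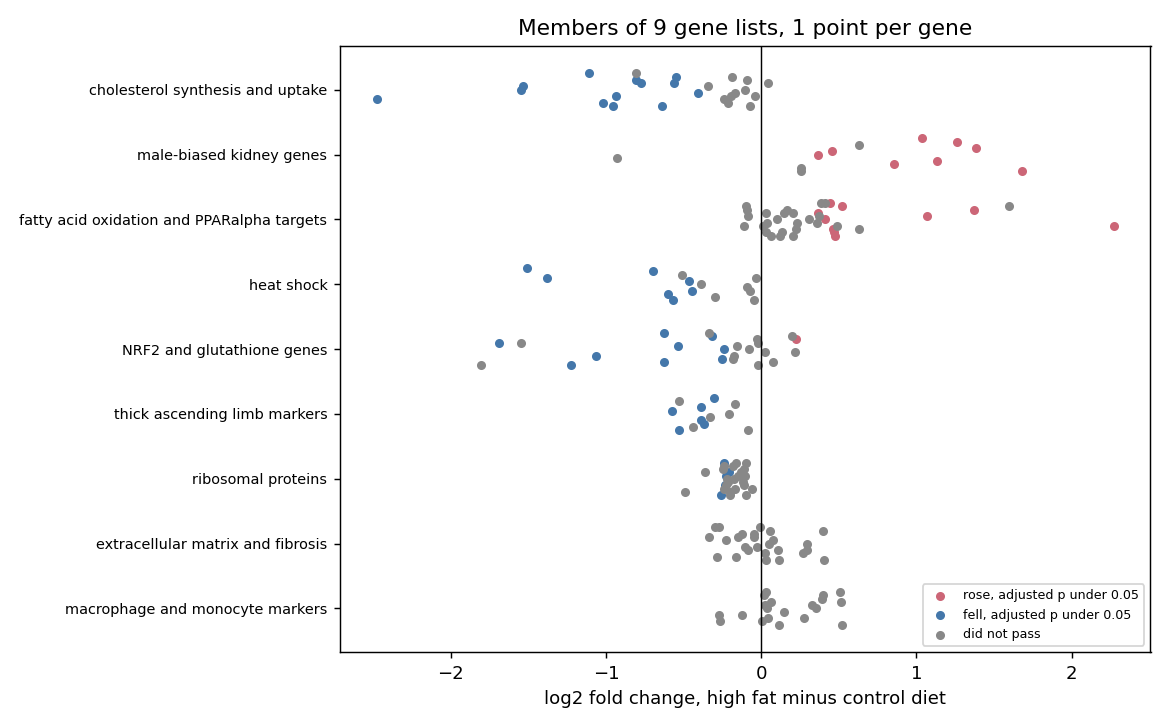
Log2 fold change, high fat minus control diet (horizontal axis), of each tested member of 9 gene lists (vertical axis). Red and blue points passed at an adjusted p under 0.05, and grey points did not. The cholesterol list holds 13 falls and no rise, and the fibrosis and macrophage lists hold no called gene.

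Calls differed among the lists of inflammation and scarring, from 0 of 26 fibrosis genes to 3 of 16 cytokine genes, beside 9.98% of all tested genes. Of 22 interferon-stimulated genes 1 fell in edgeR and 7 had an unadjusted p under 0.05. The fibrosis, macrophage, cytokine and interferon lists had adjusted p = 0.962, 0.172, 0.208 and 0.938 (camera, preset correlation). None of them passed with an estimated correlation. None of 26 extracellular matrix and fibrosis genes passed in edgeR, where 4 had an unadjusted p under 0.05; DESeq2 called 1 and limma-voom 0. None of 20 macrophage and monocyte markers passed in edgeR (3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom), and none of 14 endothelial markers (0 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom). Igj (now Jchain), the joining chain of antibodies, was the 1 of 10 lymphocyte markers that rose, from 0.523 ± 0.217 to 2.02 ± 0.530 CPM (SD, n = 4). Il34, Nfkbia and Cxcl1 rose among 16 cytokine genes, with Cxcl1 lost without control J or L or high fat A or B (adjusted p up to 0.0721 in edgeR). Of 18 tubular injury genes Gdf15 rose by 0.71 and Cp fell by 0.33 on the log2 scale, with 7 at an unadjusted p under 0.05 and none called without control J. Gdf15 kept its call in 2 of 8 fits without a library (adjusted p up to 0.0869, without high fat F) and Cp in 1 (up to 0.115, without high fat F). That list had an adjusted p = 0.363 (camera, preset correlation) and adjusted p = 0.698 with an estimated correlation. Havcr1 and Lcn2, of the same list, did not pass (adjusted p = 0.77 and 0.069 in edgeR). Of 19 cell cycle genes, 7 rose, 1, Mcm6, fell and 11 did not pass, and without control J and high fat G 4 rose. Mki67 rose from 5.17 ± 1.49 to 12.4 ± 2.44 CPM and Top2a from 2.79 ± 0.487 to 5.54 ± 0.899 CPM (SD, n = 4). That list had an adjusted p = 5.86e-07 (camera, preset correlation) and adjusted p = 0.217 with an estimated correlation, and it was not called among genes with a mean of at least 5 CPM. The circadian genes Per1, Dbp and Arntl did not pass (adjusted p = 0.72, 0.72 and 0.21 in edgeR).

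The summed RNA of the fat, muscle and red cell lists was not shown to differ between the diets. The white adipocyte sum was 582 ± 111 CPM on the high fat and 469 ± 79.99 CPM on the control diet (SD, n = 4; exact two-sided permutation p = 0.171), and the muscle sum 25.3 ± 1.95 against 24.2 ± 3.11 CPM (SD, n = 4; exact two-sided permutation p = 0.514). The white adipocyte sum says little about fat carried in with the cortex. Only 9 of the 19 members had enough counts to be tested, and the adipocyte genes Adipoq and Cfd held 10 and 47 counts over all 8 libraries. The muscle sum says as little about muscle carried in. Fewer than 4 of its 13 members had enough counts to be tested. The muscle genes Ckm and Acta1 held 9 and 28 counts over all 8 libraries. Of the 9 tested white adipocyte markers Lipe, a lipase gene, rose, by 0.43 on the log2 scale. The white adipocyte list had an adjusted p = 0.0359 (camera, preset correlation) and adjusted p = 0.245 with an estimated correlation. It lost its call at the preset correlation without control I, control L or high fat G, and with no filter on low counts. The red cell sum was 1580 ± 1441 against 959 ± 463 CPM (SD, n = 4; exact two-sided permutation p = 0.457), with high fat G at 3737 and control J at 1653 CPM. Over these sums and those of brown fat, adrenal gland and liver, the smallest adjusted p was 0.343 (exact permutation). The brown fat and adrenal sums are limited in the same way. Only 5 of 12 brown fat markers and fewer than 4 of 14 adrenal markers had enough counts to be tested.

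The authors' deposited table by gene symbol lists 1133 genes, 540 higher and 593 lower on the high fat diet. Of these, 1126 were tested here, all in the same direction, and 966 were called, against 112 expected for independent lists of these sizes; 502 genes called here were not in it. Both rest on the same libraries, so the overlap is not independent evidence. The authors' deposited table by Ensembl gene lists 1175 genes, of which 1114 were tested here, 1110 in the same direction, and 918 were called.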

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

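The tests of control J, of the proximal tubule and segment shares, of shared reads and of the sex of the mice, the spread between libraries for the ribosomal list, and the split count for list members, were chosen after the results they bear on had been seen; the tests of the length trend and the split counts for genes and lists were set before. Single libraries stood far from the other 3 of their diet in 20 of the 284 groups examined, where chance alone gives about 14.2.

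Control J stood apart in Rn45s, at 50.3% of its counts against 5.70% in the next control, and in Lars2, a gene that can collect mitochondrial ribosomal reads, at 12.2% of the remaining counts against 1.72%. Without this library 785 of the 1468 called genes kept their call and direction, against 734 without control I, 864 without control L and 1163 without control M, so these 785 calls do not come from ribosomal RNA in control J. For the other 683 its part cannot be told apart from the loss of a library. A trend of counts with transcript length fails to account for most of the 1468 called genes, since 1345 of them kept call and direction once it was removed. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes, the diets themselves with 1468, and the highest other split gave 1. This argues against chance for the gene count but cannot exclude it. A match in 1 of 35 is the least possible, and the other splits mix the diets, so a real difference lowers their calls. Beside chance, the diet and any unrecorded difference in handling between the groups stay open. The design does not part these, so the effect of the diet remains a hypothesis.

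The lower ribosomal protein genes may come from the length trend, since these transcripts are short. After that trend was removed the list's median log2 change was -0.14, with a bootstrap SE of 0.02, against -0.20 before, and its adjusted p was 8.38e-05 (camera, preset correlation); 3 members were called in place of 5. With an estimated correlation its adjusted p was 0.391. That bootstrap takes genes as independent; between libraries the list's median differed by -0.18 ± 0.06 (SE, n = 4 per diet; exact two-sided permutation p = 0.0571) before the trend was removed and by -0.12 ± 0.03 (p = 0.0286) after, which lies within 1 SE of the bound of -0.1 set beforehand. Under the rule set beforehand, which used the bootstrap SE alone, the list stayed below that bound. The need to pass it between libraries was added after the values were seen. The remaining -0.12 ± 0.03 between libraries argues against the length trend, as removed here, as the whole cause. Whether the remainder passes the bound of -0.1 cannot be told with these libraries. RNA quality that acts on these transcripts by another route than length was not tested and stays open.

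The rise of male-biased genes could reflect more proximal tubule in the high fat samples, where these genes are expressed. The median log2 change of 37 proximal tubule transport genes was 0.052, against 0.74 for the male-biased list, and the bootstrap 95% interval of 0.5 times the male-biased median minus the transport median, 0.10 to 0.61, excludes 0. Between libraries that difference was 0.32 ± 0.06 (SE, n = 4 per diet). This argues against a larger share of proximal tubule as the whole cause. A part is left open, since the median of the S1 and S2 markers was higher in every high fat library than in any control library (a mean difference of 0.15, exact two-sided permutation p = 0.0286) and the medians of the thick ascending limb and collecting duct lists were lower. For the segments the tests do not decide: the median was 0.16 for the S1 and S2 list and 0.17 for the S3 list, where 3 of 12 members rose and 3 fell, and the same intervals, -0.12 to 0.63 and -0.23 to 0.99, include 0. Between libraries the differences were 0.19 ± 0.05 (SE, n = 4 per diet; exact two-sided permutation p = 0.0286) and 0.24 ± 0.10 (p = 0.0857), which go against a segment share as the whole cause, but they do not cover the spread between so few markers. A larger share of the S1 and S2 segments or of the S3 segment therefore cannot be told apart from a change within cells with these few markers. The S3 list also shares Slco1a1 with the male-biased list and Slc7a12 with the female-biased list. Its comparison with the male-biased list is therefore not independent, although the bootstrap took it so. Reads shared between Cyp4a12a and Cyp4a12b are not the source either, since 5 of the other 9 members rose with Cyp4b1 set aside. The labels do not state the sex of the mice beyond an unexplained M in each title. However, 0 of 8 libraries held more Xist than the sum of 4 Y-linked genes (Xist at most 1.003 CPM, that sum at least 175 CPM). All 8 libraries thus looked male, which argues against a difference in sex between the diets. A shift in hormone signalling in response to the diet is a hypothesis that stays open and untested, and Kap, an abundant androgen-regulated gene, did not pass.

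The other libraries that stood apart are given as values. The red cell sum was 3737 CPM in high fat G (next 981) and 1653 CPM in control J (next 763), and the adrenal sum was 50.9 CPM in control J (next 55.4). In high fat F, Synpr was at 44.9 CPM (next 11.9), Gusb at 128 (66.5), Ppp1r1a at 54.2 (61.6), Kcnj1 at 175 (196), Lipe at 20.8 (23.5) and Dusp1 at 25.1 (37.2). In high fat A, Fdps was at 13.0 CPM (11.002) and Hspa1a at 10.2 (11.3), and in high fat B Bhmt was at 2.26 (1.52). In control J, Kap was at 14065 CPM (18502) and Itga8 at 24.0 (22.4). In control L, Scd1 was at 66.3 CPM (76.3) and Ntng1 at 0.214 (0.472), and in control M Cyp2b10 was at 1.10 CPM (0.339) and Rps20 at 119 (134). In the Ensembl table, which the comparison did not use for tests, Igkc, an antibody light chain gene, averaged 5.87 FPKM on the high fat and 1.38 FPKM on the control diet, and Olfm4 10.9 and 7.52 FPKM; every high fat library lay above every control library for both. That table lists only genes the authors called, so the difference is not independent of their selection.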

How the results depend on the processing

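The settings added after the data were seen were the robust fit, the removal of ribosomal and structural RNA, the removal of the length trend, rescaled FPKM, log2 FPKM with pseudocounts of 1 and 0.01, leaving out control J with high fat G, and a red cell sum over fewer genes. The 1468 called genes (715 up, 753 down) kept their direction under every setting in which they were tested. Leaving out 1 library gave 737 to 1501 genes (426 to 795 up, 298 to 706 down), and without control J and high fat G 419 were called (251 up, 168 down), with fewer libraries in each fit. limma on log2 FPKM called 76 (52 up, 24 down), 84 (56 up, 28 down) with a pseudocount of 1 in place of 0.1, 73 (49 up, 24 down) with 0.01 and, once FPKM was rescaled without Rn45s, 827 (371 up, 456 down); unrescaled FPKM shifted the median of all genes by 0.14 on the log2 scale, and 68.4% of its calls were rises against 48.7% in the main test. An adjusted p under 0.10 gave 2550 (1223 up, 1327 down), and a fold of at least 1.5 gave 405 (257 up, 148 down). Of 664 tested list members, 152 were called, 26 with log2 FPKM at each pseudocount and 68 without control J and high fat G. The list tests called 15 lists at the preset correlation, 0 at the estimated correlation (8 at an unadjusted p under 0.05) and 13 with fry. At the preset correlation the white adipocyte list lost its call without control I, control L or high fat G and with no filter, the mesangial list without control J or high fat B, the intercalated list without high fat A, and the cell cycle list at a mean of 5 CPM. Of the 35 splits of the 8 libraries, 9, the diets included, called at least 15 lists, and the highest other split called 19. Chance therefore cannot be excluded for the number of lists. For list members called singly, 1 of 35 splits gave as many, the diets with 152, and the highest other gave 0. That count adds no separate evidence, since no other split called more than 1 gene in all. A match in 1 of 35 is the least possible, and the other splits mix the diets. Over 130 named genes and 2674 refits, 2177 stayed on the same side of the threshold, 476 lost the call, 4 gained it and 17 changed direction, none of them in a called gene. Of 119 called named genes, 90 kept the call without each library in turn. The direction turned for Agt (0.0045 at a mean of 5 CPM, 0.0074 without the length trend, 0.069 without control J and high fat G, 0.14 on log2 FPKM, 0.12 with a pseudocount of 1 and 0.14 with 0.01, and -0.075 to 0.038 without 1 library), for Havcr1 (-0.37, without high fat F, to 0.53), Per1 (-0.011, without high fat G, to 0.46) and Dbp (-0.20 to 0.016, the latter without high fat B, 0.032 on log2 FPKM, 0.030 with a pseudocount of 1 and 0.032 with 0.01), all uncalled. The white adipocyte and muscle differences turned to -0.29 and -0.15 with the median over the list, and the red cell difference to -0.060 without high fat G, with up to 0.77 without control J; the causes were not tested. Isoforms could not be compared because the table holds 1 line per gene. In the simulation, changes of 1.3-fold were often below what the test could call.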

Other observations

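Gene families by symbol root were examined after the data were seen, over 335 families with at least 6 tested members, some of which also stand in the fixed lists. In the histone family 7 of 54 members rose and none fell, 3 of 9 axonemal dynein genes (Dnahc) rose and none fell, and 5 of 32 kinesin genes rose and none fell. In the Serpina family, which holds serum protease inhibitors, 4 of 6 members fell, and of the interferon-induced guanylate-binding genes (Gbp) 3 of 9 fell. Of the Gstm glutathione transferases 3 of 6 fell, and of mitochondrial ribosomal proteins 5 of 47 (Mrpl) and 3 of 29 (Mrps) fell. These counts stand beside 9.98% called over all tested genes, a share that the Mrpl and Mrps families hardly exceed. The camera test with preset correlation called 17 families, with adjusted p = 4.18e-04 for histones and 0.0054 for Gbp; with an estimated correlation 0 were called, at adjusted p = 0.86 for both. Reads may be shared within these families, and for the fixed lists 9 of 35 groupings of the libraries, the diets included, called as many lists, so these counts are values only.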
